A study of Mus musculus with 2 samples.

How the data were processed

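The deposited files are 2 count matrices, 1 per library, with whole-number UMI counts for 46984 features (mouse genes and the tdTomato transgene) in 6794880 barcodes each. Per the labels, islet cells of 3 animals per genotype were pooled, sorted for tdTomato and captured with the 10x 3′ kit, version 3.1, after dissociation with actinomycin D, which blocks new transcription. Per the submitters' processing notes, STARsolo (STAR 2.7.3a), Seurat 4.3.0.1 and the GRCm38.p6 genome were used. The deposited counts are unfiltered, and no cell filter, doublet removal or normalization by the authors is in them. Of the 46984 feature IDs 37902 match the GENCODE vM21 annotation of GRCm38 exactly and 46488 without the version suffix, and gene positions were taken from it by the unversioned ID.

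Each library was read from its own matrix, and the genotype was taken from the labels. Barcodes with at least 1000 UMIs numbered 4291 in control and 8431 in Isl1CKO. Cells needed at least 1000 UMIs, 500 genes and at most 15% mitochondrial UMIs. Scrublet, run per library through scanpy 1.11.5 with an expected rate of 0.05 and its automatic threshold, marked 249 of 4219 control cells (5.90%) and 0 of 8231 Isl1CKO cells, so it did not work in Isl1CKO. With the control threshold of 0.185 it would mark 360 Isl1CKO cells (4.37%), an alternative chosen after seeing the data. Kept cells of both libraries were scaled to 10000 UMIs, log-transformed, reduced to 2000 variable genes and 30 principal components and joined by 15 neighbours. Leiden clustering (leidenalg 0.10.2) at resolution 1.0, without integration, gave 17 clusters.

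A cluster was named from 14 fixed lists of cell type markers when at least 3 markers of 1 list were at least 1.5-fold higher than in the other cells of the same library and found in at least 10% of its cells, more than of any other list. At least 1 of them had to be among its top 10 genes by fold, with no other list ahead there. There were 7 lists that named clusters, and 4 clusters stayed unnamed. Cluster 10, with 53 control and 481 Isl1CKO cells, had a median UMI count under 1 part in 3 of its library's and was left out, as were 54 control and 221 Isl1CKO acinar-like and macrophage-like cells (clusters 14 and 15). The other clusters are called endocrine. Isl1CKO clusters 3, 4 and 8 are the unnamed endocrine ones, led by Lincpint and Neat1, by Pyy and Tac1, and by Neurog3 and Ffar2. A class was compared only with at least 50 cells in each library, which left out delta-like and gamma-like cells.

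UMIs were summed per library over endocrine, alpha-like and beta-like cells. Scale factors were TMM from edgeR 4.0.16 in R 4.3.3. The log2 ratio used 1 added to each summed count, and its interval is the exact conditional 95% interval of a ratio of Poisson counts. CPM have exact Poisson intervals and shares exact Clopper-Pearson intervals. These cover counting error only, and cells are not replicates, so no test between genotypes was made. Genes were measured at 5 CPM or more in at least 1 library. A gene was called higher or lower at 2-fold or more with an interval excluding 1. A gene at 0 in 1 library has a bound taken against 3 counts in that library.

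The genes named are all members of the fixed lists, of which those with large or contrasting values are printed, and the 12 highest and 12 lowest ratios per comparison among genes with at least 20 CPM and 20 UMIs in 1 library and the same direction under each scaling and with doublets kept. Some of these genes are not reported here. The gene lists, markers, thresholds and alternatives other than those named as added were written before the data were examined. The lists are islet hormones, beta cell function and maturity, alpha cell, delta cell, islet transcription factors, endocrine progenitor, pancreatic progenitor, beta cell dedifferentiation, genes repressed in mature beta cells, enteroendocrine and neuropeptide, insulin secretion and exocytosis, glucose metabolism, oxidative phosphorylation, unfolded protein response, immediate early, interferon and antigen presentation, cell cycle, neuronal, antioxidant and hypoxia, and sex-linked genes. They overlap: 11 of the 17 dedifferentiation genes, 9 of the 25 enteroendocrine and 7 of the 22 endocrine progenitor genes are also in another list. Each list's median was placed among 10000 random lists of the same size drawn from 50 measured genes of nearest expression, a description of these libraries. Another scaling shifts a list and its random lists alike, but measured and matched genes were chosen with TMM-scaled CPM only.

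Relative to TMM, unscaled CPM moved all log2 ratios by 0.53 over endocrine, 0.39 over alpha-like and 1.13 over beta-like cells. Leaving hormone genes out of the totals moved them by -0.21, -0.31 and -0.24, and DESeq2 1.42.0 size factors by -0.02, 0.02 and -0.02. The sign of a list's median held under all of these for 10 of 19 lists over endocrine cells, 14 of 19 in alpha-like and 10 of 18 in beta-like cells; the others lie near 0.

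The free RNA profile came from barcodes of 1 to 100 UMIs (3405226 UMIs in control, 6141338 in Isl1CKO). Its share of a cell's UMIs was estimated from acinar genes at 29.2% in control and 1.98% in Isl1CKO. The control value is inflated by acinar genes that control delta-like cells express, Cela1 among them, and was 11.1% with a narrower set of acinar genes (1.97% in Isl1CKO). An upper estimate from insulin in alpha-like cells was 2.14% and 3.36%. Cell sex was read from Xist against Ddx3y, Eif2s3y, Kdm5d and Uty. Shares of cells with a UMI were also given after thinning each cell to 3000 UMIs, leaving 3748 control and 7284 Isl1CKO endocrine cells.

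Alternatives were unscaled CPM, CPM without hormone genes, DESeq2 factors, doublets kept, a mitochondrial limit of 10%, a minimum of 2000 UMIs and 1000 genes, the OrdMag minimum, free RNA subtracted, cells thinned or weighted equally, male cells, hormone limits of 0.5% and 5%, resolutions of 0.5 and 1.5, clustering without hormone genes or per library, and no filter on low counts. Added after seeing the data were female cells, a male-cell split of hormone shares, a shared Scrublet threshold, free RNA estimated from the narrower acinar set or from insulin in alpha-like cells, and leaving out Isl1CKO cells in control clusters or the 7 enterochromaffin-like cells. In the planned male-cell setting control cells with both Xist and Y-linked UMIs were kept. The computation was tested on simulated counts of the endocrine control library over 46984 genes. These were Poisson counts scaled by the known simulated shift, so neither TMM nor variation between animals was tested. Intervals covered the true ratio for 94.0% to 98.0% of changed genes and 95.5% of unchanged genes. All 4-fold changes passed the size rule, as did 60.0% of 0.5-fold and 42.0% of 2-fold changes and 0% of unchanged genes.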

Results

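The series measured single-cell RNA in pancreatic islet cells of 1-month-old mice. It asked what happens to islet endocrine identity without Isl1, a LIM-homeodomain transcription factor of islet endocrine cells. There were 2 libraries, 1 per genotype, each from cells of 3 pooled animals sorted for tdTomato, a red fluorescent reporter. Control animals carried a Neurod1-Cre allele, which acts in endocrine cells, and 1 floxed Isl1 allele. Isl1CKO animals carried the same Cre allele and 2 floxed Isl1 alleles. The control library held 48685758 UMIs (unique molecular identifiers, 1 per captured RNA molecule) and the Isl1CKO library 86086781. After filtering, 3970 control and 8231 Isl1CKO cells remained, with medians of 8838.5 and 8137 UMIs and of 2428 and 2862 genes per cell. Of these, 3863 and 7529 were endocrine cells. With 1 library per genotype no difference below has a replicate check and no p-value is given. All intervals are 95% intervals and cover counting error only. Expression is in CPM (UMIs relative to the total of the summed cells, scaled by TMM), and log2 ratios are Isl1CKO over control.

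Isl1 transcripts were present at similar levels in both libraries. Isl1 (ENSMUSG00000042258.13, GRCm38 chromosome 13, 116298281 to 116309689) stood at 364 CPM (357 to 370.5) in control endocrine cells and at 294 CPM (290.4 to 297) in Isl1CKO endocrine cells, a log2 ratio of -0.31 (-0.34 to -0.28). The ratio was -0.38 in male cells and -0.08 in female cells, and with CPM not scaled by TMM it was 0.22, so its direction was not settled. Isl1 stood at 337 and 376 CPM in control and Isl1CKO alpha-like cells and at 133 and 150.5 CPM in beta-like cells. At least 1 Isl1 UMI was found in 85.1% of control and 86.7% of Isl1CKO endocrine cells, and in 57.9% and 60.8% after thinning each cell to 3000 UMIs. The non-endocrine cells of cluster 15 served as a reference for such shares. It is not a clean background. Without scaling, tdTomato was at 838 CPM in its control and 1563 CPM in its Isl1CKO cells, against 1088 and 5379 CPM in endocrine cells. Cluster 15 cells were named macrophage-like but included stromal cells: at resolution 0.5 a cluster led by Sparc, Mgp and Col3a1 held 36 control and 32 Isl1CKO cells, and 4 and 15 cells were macrophage-like. Cluster 15 cells had an Isl1 UMI in 39.5% (control, median 5560 UMIs) and 24.5% (Isl1CKO, median 3371 UMIs) of cases, against medians of 8903 and 8502 UMIs in endocrine cells. The labels do not state which exons are floxed, and counts of transcript 3′ ends outside a deleted part check nothing, so the genotypes rest on the labels. Neurod1, the gene that drives the Cre, stood at 241 and 301 CPM (log2 ratio 0.32).

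Transcripts of both sexes were present in both libraries. The labels describe the control pool as males and the Isl1CKO pool as females and males. Of the control endocrine cells, 23.2% (21.9 to 24.6) had UMIs of Xist, the X-inactivation RNA of female cells, and none of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. Y-linked UMIs without Xist were found in 41.4% (39.9 to 43.0), and both in 1.92%. In Isl1CKO these shares were 66.5% (65.4 to 67.5), 20.5% (19.6 to 21.4) and 3.32%. Cells with Xist alone are called female cells below and cells with Y-linked UMIs alone male cells, and values within each sex are given beside the pooled ones. Over all endocrine cells Xist was at 171 and 363 CPM (log2 ratio 1.08). The list of sex-linked genes had a median log2 ratio of -0.80, with medians of -0.55 in alpha-like and -0.59 in beta-like cells. Its medians within each sex are not given. Female cells were defined by having no Y-linked UMIs and male cells by having none of Xist, so those medians were fixed beforehand. Isl1CKO cells of the 2 sexes lay in different clusters. Isl1CKO clusters 0, 3, 4, 5 and 6 were between 99.4% and 100% female among cells of known sex, and clusters 7, 8 and 9 were 1.16%, 1.94% and 1.29% female. Control clusters mixed the sexes, with 40.8% and 50.6% female in alpha-like clusters 1 and 11 and 21.8% in beta-like cluster 13. The genotype difference was therefore also a difference in sex composition. Within each sex it rested, by the labels, on at most 2 Isl1CKO animals. The labels give no female control animal, and if the control pool of 3 held both sexes, each sex rested on at most 2 control animals.

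**Figure D1:**
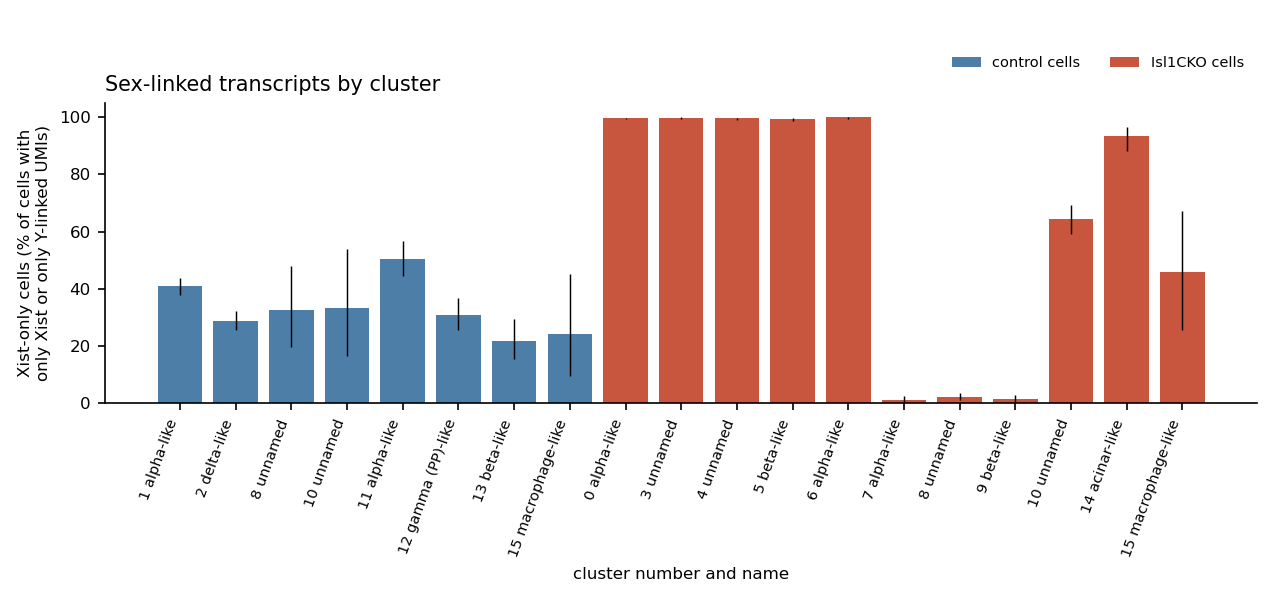
Share of female cells among cells with only Xist or only Y-linked UMIs, in percent, for each cluster and library (bars) with 95% exact binomial intervals (lines). Isl1CKO clusters 0 and 3 to 6 lie between 99.4% and 100%, clusters 7 to 9 between 1.16% and 1.94%, and clusters 14, 10 and 15 at 93.4%, 64.4% and 45.8%, while control clusters lie between 21.8% and 50.6%.

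Glucagon, somatostatin and pancreatic polypeptide transcripts, abundant in control islet cells, were scarce in the Isl1CKO library, while insulin transcripts were found in cells of both. In 50.3% (48.7 to 51.9) of control endocrine cells Gcg, which encodes glucagon, took at least 1% of the UMIs, against 2.26% (1.93 to 2.62) in Isl1CKO. For Sst (somatostatin) the shares were 32.8% (31.3 to 34.3) and 0.146% (0.0730 to 0.261), and for Ppy (pancreatic polypeptide) 47.2% (45.6 to 48.8) and 0.133% (0.0637 to 0.244). Insulin, Ins1 and Ins2 together, was at this level in 7.12% (6.33 to 7.98) of control and 12.0% (11.3 to 12.8) of Isl1CKO cells. Beta-like cells were few in control, 221 of 3863, and a loss of beta cells before capture stays undecided (last paragraph). The difference in insulin shares, also within each sex, therefore cannot be read as an effect of genotype. Ghrl (ghrelin) reached it in 0 of 3863 control cells, which allows a share of up to 0.0954%, and in 2 Isl1CKO cells. Cells with 2 or more hormones made up 37.3% of control and 0.106% of Isl1CKO cells. None of these hormones reached 1% in 2.25% (1.81 to 2.77) of control and 85.5% (84.7 to 86.3) of Isl1CKO cells.

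The same order held within each sex. In male cells the control and Isl1CKO shares were 46.4% and 1.88% for Gcg, 33.8% and 0.130% for Sst, 48.8% and 0.130% for Ppy, 8.12% and 17.3% for insulin, and 1.81% and 80.6% for none. In female cells they were 61.7% and 2.40%, 24.8% and 0.180%, 38.8% and 0.160%, 4.8% and 10.0%, and 1.90% and 87.4%. With a limit of 5% of UMIs the insulin shares were 5.38% in control and 6.07% in Isl1CKO cells. The shares for Gcg were then 49.0% and 0.146%, for Sst 30.3% and 0.0797%, for Ppy 26.7% and 0.0398%, and for none 3.81% and 93.7%, while 579 of 3863 control and 1 of 7529 Isl1CKO cells had 2 or more hormones. With a limit of 0.5% Gcg was at 51.8% and 4.08%, Ppy at 51.6% and 0.173%, and 2 or more hormones at 43.3% and 0.173%. RNA free in the droplets of the control library was 6.88% Ppy, 16.7% Gcg and 2.73% Sst. Insulin in control alpha-like cells, if all of it were free RNA, put the free share at 2.14% of a cell's UMIs, which would add 0.358% of UMIs as Gcg and 0.147% as Ppy, below the 1% limit. Estimates from acinar genes were higher, at 11.1% and 29.2%. Either, if alike in all cells, would take Gcg past the 1% limit in every control cell, while 50.3% reached it.

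**Figure D2:**
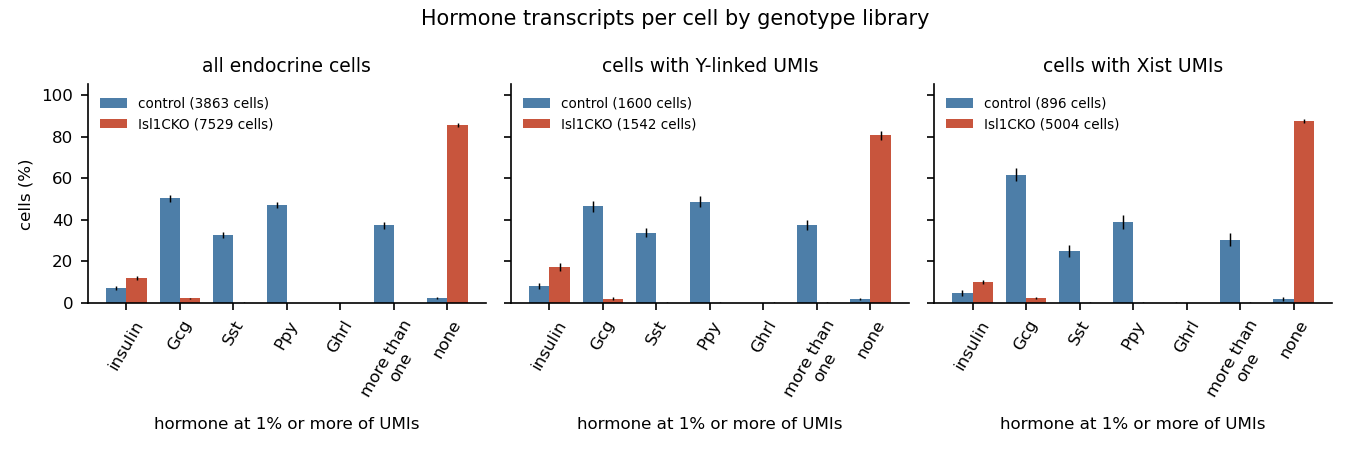
Percent of endocrine cells in which each hormone took at least 1% of the UMIs, for control and Isl1CKO (bars) with 95% exact binomial intervals (lines), over all cells and within each sex. Cells with none of the hormones made up 2.25% of control and 85.5% of Isl1CKO cells.

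Clusters named from fixed marker genes set which cell classes could be compared. Alpha-like cells numbered 1909 in control (clusters 1 and 11) and 3074 in Isl1CKO (clusters 0, 6 and 7, with 7 cells in cluster 11). Beta-like cells numbered 221 in control (cluster 13, with 1 cell in cluster 9) and 1563 in Isl1CKO (clusters 5 and 9, with 17 cells in cluster 13). Of these, 112 control and 474 Isl1CKO cells were male, and 31 and 815 were female. Under other filters and clusterings beta-like cells numbered 218 to 345 in control and 1276 to 2374 in Isl1CKO. Each class lay mostly in different clusters in the 2 libraries, and values within each class are compared below. Delta-like cells, named from genes such as Sst and Hhex, numbered 1223 in control and 9 in Isl1CKO, and gamma-like cells, named from Ppy and Pyy, 419 and 3, too few in Isl1CKO for a comparison. Unnamed clusters held 2.36% of control and 38.2% of Isl1CKO endocrine cells (0% to 4.28% and 28.4% to 41.5% under other filters and clusterings). The genes that define these clusters differ between the libraries, and Isl1CKO clusters were named relative to other Isl1CKO cells, so the sizes of the classes are not compared.

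Over all endocrine cells the transcripts of the islet hormones were far lower in the Isl1CKO library. Ppy (GRCm38 chromosome 11, 102099930 to 102101319) was at 84959 and 101 CPM, a log2 ratio of -9.72 (-9.75 to -9.69), and the related gut and islet peptide Pyy had a ratio of -8.92. Sst (chromosome 16, 23889573 to 23890958) had a ratio of -9.09 and Gcg (chromosome 2, 62474530 to 62483650) one of -7.67, from 211808 to 1039 CPM. Ins1 (chromosome 19, 52264297 to 52265476) and Ins2 (chromosome 7, 142678656 to 142743381), the mouse insulin genes, had ratios of -2.59 and -2.06. Iapp, the beta cell peptide amylin, had a ratio of -0.97. Of the 8 hormone genes 6 were at least 2-fold lower with an interval excluding 1 (the rule used for every such count), and Ghrl was higher. Their median log2 ratio was -5.13, below all 10000 random lists of matched expression, and it was -4.99 in male and -4.78 in female cells. Without the 36 Isl1CKO cells in clusters with more control cells the ratios of Sst and Pyy were -10.61 and -9.72. These values over all endocrine cells combine the make-up of the libraries with levels per cell.

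Beta cell function and delta cell genes were lower as groups. Of the 17 measured beta cell function genes 10 were lower and 1 higher (median -1.19, male -0.48, female -1.47). They included Abcc8, a subunit of the ATP-sensitive potassium channel (254 and 7.71 CPM, log2 ratio -5.04), and Pdx1, a beta cell transcription factor (-1.69). All 6 measured delta cell genes were lower (median -4.37, male -4.69, female -4.82), among them the transcription factor Hhex (-2.52) and Rbp4, a retinol carrier (-3.65). Of the 13 alpha cell genes 5 were lower and 3 higher (median -0.25, percentile 5.63 among random lists, male 0.22, female -0.73). General islet transcription factors were at a median of 0.33 (percentile 95.8, male 0.30, female 0.34), with 2 of 19 higher and 2 lower.

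By size alone, the genes furthest lower after Ppy, Sst and Pyy were Arg1 (-7.95), Ptn, which encodes the growth factor pleiotrophin (-7.84), Gcg, Gap43, a growth cone protein (-7.65), Mest (-6.23), the epithelial transcription factor Ehf (-5.81), Pappa2, a protease of IGF binding proteins (-5.56), and Mef2c (-5.20). The genes furthest higher were Gip, which encodes a gut incretin (7.89), Ghrl (5.85), the transcription factor Klf15 (5.23), the neuropeptide gene Cartpt (5.16), the lipid droplet protein gene Cidea (4.98), Rprml (4.92), the ectonucleotidase Nt5e (4.81), S100z (4.72), the prostaglandin receptor Ptger3 (4.55), Arrdc4 (4.47) and Fam107b (4.02). Nearly all Gip UMIs of Isl1CKO endocrine cells, 98.9%, came from 7 cells of cluster 16, as did 83.5% of Ghrl and 65.7% of Cck UMIs. Only 42.9% of the 7 cells had Gip UMIs, 28.6% Ghrl UMIs and 42.9% Cck UMIs. Without those 7 cells the ratios of Ghrl and Cck were 3.25 and 4.34, and Gip was at 0.0611 and 0.233 CPM (2 and 21 UMIs). Of these named genes all but Gip (male -0.26) had the same sign in both sexes. Klf15 was at a ratio of 2.11 in male and 6.37 in female cells, and Arrdc4 at 2.76 and 5.00.

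Gut hormone and neuropeptide genes formed the group with the highest median. Of 13 measured members 9 were higher and 2 lower, with a median log2 ratio of 2.00, above all random lists, of 2.66 in male and 1.84 in female cells, and of 1.54 without the 7 cells of cluster 16. The higher members included Cartpt, Sct (secretin, 3.74), Tac1 (tachykinin, 3.05), Slc18a1, a vesicular monoamine transporter (2.00), and Fev, a transcription factor of serotonergic and endocrine precursor cells (63.2 and 184 CPM, 1.54). Scg2, a secretogranin, was lower (-2.86). The granins Chga (2.29) and Chgb (2.20), proteins of secretory granules, were higher.

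Progenitor genes went in both directions. Of 16 measured endocrine progenitor genes 6 were higher, namely Fev, Sox4 (1.20), Btg2 (1.95), Cdkn1a, a cell cycle inhibitor (3.19), Cck, a gut hormone (5.88), and Chgb. The factor that starts the endocrine lineage, Neurog3, was lower at 33.3 and 7.49 CPM (-2.15, interval -2.30 to -2.02), as was the corepressor Cbfa2t3 (-2.10). The list's median was 0.28 (percentile 94.8 among random lists, male 0.43, female 0.45) and 0.07 with hormone genes left out of the totals. Earlier pancreatic progenitor genes had a median of 0.08 (percentile 45.2, male 0.11, female 0.22), with 3 of 15 higher, Vim, Dcdc2a (2.28) and Cpa1 (1.68), and 2 lower. Cpa1, a digestive enzyme gene, was also among the markers that named the acinar-like cluster, and the acinar genes Prss2 and Clps were higher by 1.74 and 1.54 in the same endocrine cells. Acinar genes made up 0.0411% of free RNA in control and 0.985% in Isl1CKO, against 0.0120% and 0.0195% of endocrine cell UMIs. The higher values of Cpa1, Prss2 and Clps may therefore reflect free RNA. Sox9, a ductal and progenitor factor, was at 12.4 and 0.166 CPM (-6.13), the Notch target Hes1 at -0.39 (positive with unscaled CPM) and Vim, an intermediate filament gene, at 3.52. A Neurog3 UMI was found in 17.8% of control and 6.71% of Isl1CKO endocrine cells, and in 8.70% and 2.86% after thinning. Among the 43 control and 49 Isl1CKO cells of cluster 15, which were not thinned, it was found in 18.6% and 2.04%. The control share was thus not above that of cluster 15. These few cells also held tdTomato and are not a clean background, so whether Neurog3 in control endocrine cells was background stays open. Neurog3 and Ffar2 led the genes of cluster 8 (678 Isl1CKO and 91 control cells) relative to other Isl1CKO cells. Its Isl1CKO cells of known sex were 1.94% female.

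Genes reported to appear when beta cells dedifferentiate were higher as a group over all endocrine cells. Of 15 measured members 8 were higher and 2 lower, with a median of 1.1, above all random lists, but of 2.06 in male and 0.09 in female cells. The higher members included Slc5a10, a sugar transporter (5.33), Vim, and Serpina7, a thyroxine carrier (2.44). Genes normally kept low in mature beta cells had a median of 0.52 (percentile 96.8, 4 of 10 higher, male 0.02, female 0.30). Immediate early genes, which respond to dissociation, had a median of 1.17, above all random lists, with 8 of 14 higher and 1 lower, but -0.06 in male and 1.27 in female cells. Egr1 had a ratio of 3.12 (male 0.35, female 3.95), Junb one of 2.05 (male -0.26, female 2.59) and Jun was lower (-1.63). Antioxidant and hypoxia genes had a median of 0.61, above all random lists, with 8 of 16 higher (male 0.11, female 0.73), among them Txnip, an inhibitor of thioredoxin (2.54), and the mitophagy receptor Bnip3 (2.56). Mitochondrial transcripts took 0.633% of the UMIs of control and 1.54% of those of Isl1CKO endocrine cells, and 0.627% and 1.68% within male and 0.625% and 1.46% within female cells. Among the other lists, the median was 0.16 for insulin secretion and exocytosis (percentile 81.1, male 0.39, female -0.04), -0.18 for glucose metabolism (4.89, male 0.03, female -0.29) and 0.07 for oxidative phosphorylation (55.0, male 0.30, female -0.08). It was 0.21 for the unfolded protein response (88.9, male 0.45, female 0.01), -0.00 for interferon and antigen presentation (37.8, male -0.24, female 0.46), 0.13 for cell cycle (64.4, male 0.05, female 0.21) and -0.20 for neuronal genes (5.17, male 0.02, female -0.22). Unscaled CPM would raise these medians by 0.53 and leaving hormone genes out of the totals move them by -0.21, so those nearer to 0 change sign.

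In alpha-like cells (mostly control clusters 1 and 11 and Isl1CKO clusters 0, 6 and 7) glucagon transcripts were far lower in Isl1CKO. Gcg was at 406648 CPM in control and 2527 CPM in Isl1CKO, a log2 ratio of -7.33 (-7.34 to -7.32), and within sex -7.61 (male) and -7.08 (female). Pou3f4, another transcription factor gene of alpha cells, had a ratio of -4.09. The alpha cell transcription factor genes Irx1 (166 and 175 CPM, ratio 0.07) and Irx2 (155 and 171 CPM, ratio 0.14) reversed direction with hormone genes left out of the totals. Isl1CKO clusters 0, 6 and 7 were named alpha-like from Gcg, Irx1, Irx2 and Ttr among other genes, and cluster 7 also from Gc, Slc7a2 and Slc38a5. Control cluster 1 was named from genes including Gcg, Irx1, Irx2, Ttr, Slc7a2, Slc38a5 and Pou3f4. The levels of these genes in the class are therefore partly set by the naming.

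Other alpha cell genes, most of them also used for the naming, went in both directions. Ttr, a thyroxine carrier, had a log2 ratio of 1.75, the vitamin D binding protein gene Gc one of 2.10, and Slc38a5, a glutamine transporter, one of 3.35 (male 4.66, female 1.02). The amino acid transporter Slc7a2 was lower (-2.29). Altogether 5 of the 13 alpha cell genes were lower and 3 higher, with a median of 0.14 (percentile 63.5, male 0.49, female -0.28). Nkx6-1, a factor of beta cells, was higher at 23.6 and 56.9 CPM (1.27), while the 13 measured beta cell function genes had a median of -1.19, below all random lists, with 7 lower and 2 higher (male -0.61, female -1.54). Among them Abcc8 had a ratio of -6.61 and Slc30a8, the granule zinc transporter, one of -1.50. Delta cell genes had a median of -4.37 (male -3.77, female -3.25), with 4 of 5 lower, and general islet transcription factors one of 0.32 (percentile 93.5, male 0.18, female 0.27).

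By size alone, the genes furthest higher in Isl1CKO alpha-like cells were Cartpt (0.715 and 129 CPM, 7.38), C1ql3, a synaptic complement-like protein gene (6.93, from 2 control UMIs, interval 5.66 to 10.56), Cidea (6.51), the RNA-binding protein gene Zfp36l1 (6.03), Ankrd34b (5.94), Klf15 (5.83), Ttyh1 (5.78), Proser2 (5.53), the deubiquitinase Usp2 (5.44), the angiotensinogen gene Agt (5.17), Rprml (5.12) and the serine protease Prss23 (4.81). All 12 were higher within each sex. The genes furthest lower were Pyy (-11.34), Ppy (-10.60), Sst (-10.17), the arginase Arg1 (-7.47), Gcg, the oxytocin receptor Oxtr (-7.10), Abcc8, Pappa2 (-6.45), Klhl13 (-6.24), Scnn1b, a sodium channel subunit (-6.07), and Igsf21 (-5.31), each lower within both sexes. With free RNA subtracted at 2.14% of control and 3.36% of Isl1CKO UMIs Pyy, Sst and Scnn1b were at -12.70, -12.76 and -6.72. At 29.2%, more than Gcg in control cells allows, the ratios of Pyy, Ppy and Sst turned positive.

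The medians of gut peptide, stress and immediate early genes lay above those of matched genes in alpha-like cells, the last of them not in male cells. Gut hormone and neuropeptide genes had a median log2 ratio of 1.41, above all random lists (6 of 10 higher, 2 lower, male 1.63, female 1.47), with Sct at 4.78 and Ghrl at 4.09. Unfolded protein response genes had a median of 0.73, above all random lists, with 6 of 17 higher and none lower (male 1.28, female 0.37), including the chaperone Hspa5 (1.04), Herpud1 (2.40) and Fkbp11 (2.20). Genes repressed in mature beta cells had a median of 0.96 (percentile 99.9, 4 of 8 higher, male 0.20, female 1.25). Antioxidant and hypoxia genes had a median of 0.93, above all random lists (7 of 16 higher, male 0.36, female 0.95), and the immediate early list a median of 0.91 (7 of 14 higher, 1 lower, male -0.47, female 1.37). Mitochondrial transcripts took 0.629% of the UMIs of control and 1.22% of those of Isl1CKO alpha-like cells. Txnip was higher in both sexes (male 1.38, female 3.94), and the metallothionein Mt1 was lower in male (-0.73) and higher in female cells (4.02).

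Progenitor lists in alpha-like cells lay within the range of the random lists. Endocrine progenitor genes had a median of 0.32 (percentile 94.0, male 0.28, female 0.57), with 5 of 16 higher, among them Fev (1.44), Cdkn1a (3.36) and Chgb (1.98), and 2 lower, Neurog3 (-3.32, and -4.65 with free RNA subtracted at 2.14% and 3.36%, but positive at 29.2%) and Cbfa2t3. Pancreatic progenitor genes also had a median of 0.32 (percentile 94.9, 2 of 13 higher, male -0.10, female 0.46). The higher members were Dcdc2a (2.12) and the acinar gene Cpa1 (2.09), beside the acinar genes Prss2 (1.86) and Clps (1.17). The acinar genes may again reflect free RNA. Dedifferentiation genes had a median of 0.70 (percentile 99.4, 5 of 12 higher, 3 lower, male 1.20, female 0.58). Chga had a ratio of 3.08. For the other lists the median was 0.00 for insulin secretion (percentile 25.7, male 0.06, female -0.17), -0.31 for glucose metabolism (0.770, male 0.22, female -0.48) and 0.14 for oxidative phosphorylation (41.9, male 0.52, female -0.06). It was 0.40 for interferon and antigen presentation (93.5, male 0.13, female 0.66), 0.91 for the 5 measured cell cycle genes (99.7, male 0.77, female 1.11), -0.36 for neuronal genes (2.80, male -0.03, female -0.64) and -4.66 for hormones (male -5.01, female -5.07). Other scalings move these medians by up to 0.39 or -0.31, so those nearer to 0 change sign.

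In beta-like cells (mostly control cluster 13 and Isl1CKO clusters 5 and 9) insulin and the genes of mature beta cells were lower. Ins1 was at 175341 and 6898 CPM, a log2 ratio of -4.67 (-4.68 to -4.66), and Ins2 at 686873 and 39724 CPM (-4.11). Iapp had a ratio of -1.39. Of 20 measured beta cell function genes 16 were lower and none higher, with a median of -3.06, below all random lists, of -2.51 in male and -3.97 in female cells. Ucn3 (chromosome 13, 3940688 to 3945349), the urocortin of mature beta cells, was at 143 CPM (129.6 to 157) and 0.443 CPM (0.236 to 0.758), a ratio of -8.23. Mafa (chromosome 15, 75745490 to 75748228), a late transcription factor of beta cells, was at 10.2 and 0.0682 CPM (31 and 2 UMIs, ratio -6.69, interval -10.34 to -5.26). Without the 17 Isl1CKO cells in control cluster 13 the ratio of Ucn3 was -9.02 and Mafa had 31 and 0 UMIs. The glucose transporter Slc2a2 (-3.27), the phosphatase G6pc2 (-5.70), Abcc8 (-3.46), Slc30a8 (-1.77) and the prohormone convertase Pcsk1 (-2.53) were lower. Clusters 5 and 9 were named beta-like from Ins1, Ins2 and Iapp and cluster 9 also from G6pc2, Slc2a2, Pdx1 and Slc30a8. Control cluster 13 was named from these except Slc30a8 and from Nkx6-1, Mafa, Ucn3 and Trpm5, so the levels of these genes in the class are partly set by the naming.

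The beta cell transcription factors Pdx1 (253 and 37.0 CPM, -2.77) and Nkx6-1 (288 and 113 CPM, -1.35) were lower in both sexes. A Pdx1 UMI was found in 84.6% of control and 43.4% of Isl1CKO beta-like cells, and in 38.5% and 14.6% after thinning, against 30.2% and 10.2% of cluster 15 cells. Median depths were 19253 and 11707 UMIs in beta-like cells and 5560 and 3371 in cluster 15 cells. For Ucn3 the shares were 50.7% and 0.576%, 16% and 0.328% after thinning, against 6.98% and 0 of 49 cluster 15 cells. Over the 21 measured islet transcription factors the median was 0.08 (percentile 71.9, male -0.02, female 0.01), with 4 lower and none higher.

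**Figure D3:**
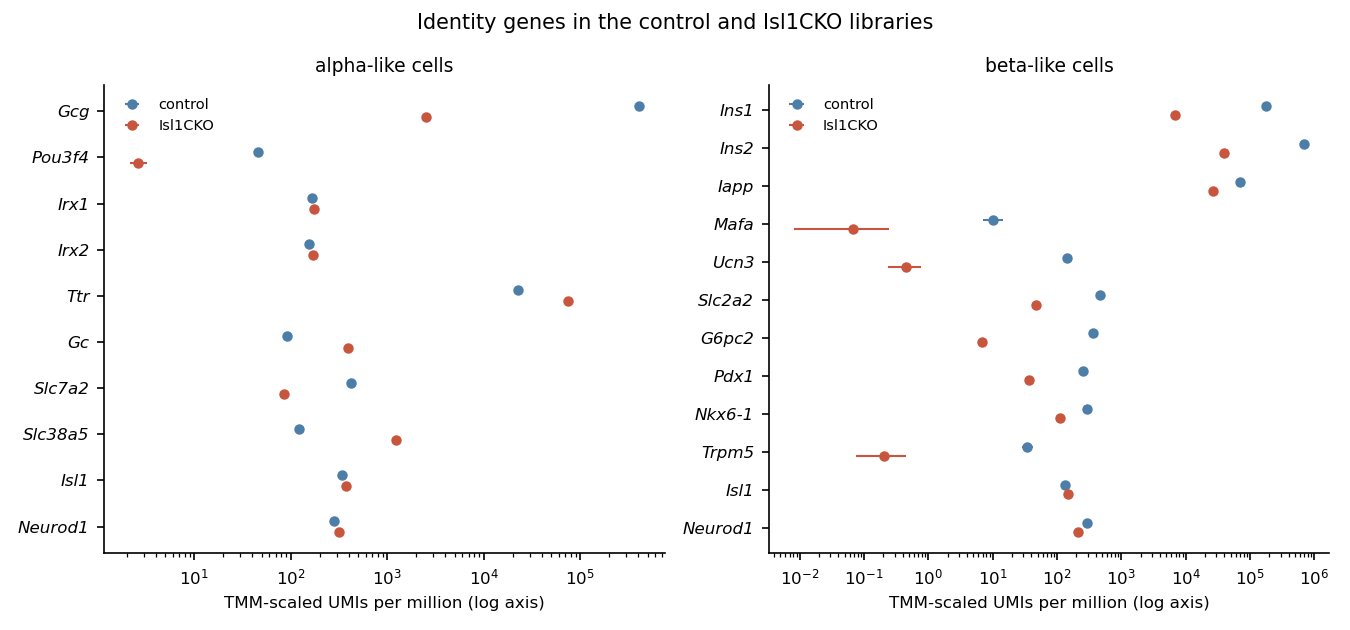
CPM of identity genes in control and Isl1CKO alpha-like (left) and beta-like (right) cells, on a log axis, with 95% Poisson intervals (lines, smaller than most points). Gcg, and Ins1, Ins2, Ucn3 and Mafa, lie lower in Isl1CKO, and Irx1 and Irx2, which were among the genes that named the alpha-like clusters, at similar levels in both libraries.

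Dedifferentiation genes were higher as a group in Isl1CKO beta-like cells. Of 15 measured members 8 were higher and 3 lower, with a median log2 ratio of 1.71, above all random lists, but of 2.35 in male and 0.49 in female cells. Higher members were Cartpt (3.42), Slc5a10 (3.74), Serpina7 (3.70), Chgb (2.72), Gc (2.12), the transcription factor gene Etv1 (1.71), Gast, the stomach hormone gastrin (2.42), and Vim. Vim had 0 UMIs in control beta-like cells and was at least 52.9-fold higher in Isl1CKO, taken against 3 UMIs in that library. The neuropeptide gene Npy had 59 UMIs in control and 0 in Isl1CKO beta-like cells and was at least 191-fold lower by the same rule. Gast was at a ratio of 4.51 in male and -2.25 in female cells. All female values in beta-like cells rest on 31 control cells. Their summed UMIs were 554954 in control and 9423587 in Isl1CKO, and 1 was added to each count. A gene with 0 UMIs in both libraries would therefore score -4.84. Negative female values of genes with few UMIs, and the sign of Gast, may come from the added count. Neurog3 was at 10.6 and 4.19 CPM (-1.37, male -1.02, female 0.66). With both genes taken at 3 UMIs the list's median was unchanged at 1.71. Endocrine progenitor genes had a median of 0.26 (percentile 91.8, male 0.11, female 0.54), with 5 of 15 higher, including Sox4 (1.91), Fev (1.97) and Cdkn1a (2.57), and 2 lower. Pancreatic progenitor genes had a median of 0.10 (percentile 60.1, male -0.13, female 0.14), with 5 of 14 higher and 3 lower. Cpa1 (2.20) was among the higher ones, beside the acinar genes Prss2 (2.04) and Clps (2.54), and all of these may reflect free RNA.

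By size alone, the genes furthest higher in Isl1CKO beta-like cells, beside Vim, were Cidea (6.10), Arrdc4 (4.69), the inhibitor of differentiation Id3 (4.63), Ptger3 (4.44), Ttc25 (4.21), Vstm2a (4.18), Fbp2, a fructose bisphosphatase (4.16), Fam107b (4.13), the sortilin family receptor Sorcs2 (3.92), Slc5a10 and Serpina7. Vim had no control UMIs and has only a lower bound, so its rank among these genes is not settled. Ttc25 and Vstm2a rest on 3 control UMIs each, with intervals of 3.07 to 6.90 and 3.04 to 6.88. The genes furthest lower were Sst (-13.14), Ppy (-10.45), Pyy (-10.28), Dapl1 (-9.45), the mitochondrial subunit gene Cox6a2 (-8.86), Ucn3, Gcg (-7.84), Arg1 (-7.80), the taste and islet channel gene Trpm5 (-7.20), G6pc2, Tmem215 (-5.37) and the protease Prss53 (-5.19). Dapl1 and Cox6a2 had 1 Isl1CKO UMI each, with intervals of -15.75 to -7.94 and -15.17 to -7.33. All 24 of these genes had the same sign in both sexes. With free RNA subtracted at 2.14% of control and 3.36% of Isl1CKO UMIs Gcg was at -6.29, Id3 at 5.29, and Sst had 0 Isl1CKO UMIs left. At 29.2%, more than control cells' Gcg allows, Gcg, Ppy and Pyy turned positive. The 7 measured hormones had a median of -7.84 (male -4.61, female -8.79), which over all cells is the ratio of Gcg. Free RNA at 2.14% would add 0.358% of UMIs as Gcg in control, against 0.00299% in Isl1CKO at 3.36%. After that subtraction 1052 control and 128 Isl1CKO Gcg UMIs were left in beta-like cells, so the Gcg ratio may partly reflect free RNA. The 6 delta cell genes had a median of -3.08 (all lower, male -3.72, female -3.28).

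The remaining lists in beta-like cells included immediate early genes with a median log2 ratio of 0.73 (male -0.64, female 1.06), 4 of 12 higher and 1 lower. Unfolded protein response genes lay below matched genes, with a median of -0.30 that was positive with unscaled CPM (percentile 0.960, male -0.31, female -0.30), where Sdf2l1 was at -2.14 and Herpud1 at 1.78. Gut hormone and neuropeptide genes had a median of 0.36 (percentile 78.9) with 4 of 10 higher and 4 lower (male 0.86, female -1.54). The negative female median may likewise come from the 1 added to each count. The median was 0.15 for alpha cell genes (percentile 55.1, 3 of 10 higher, 2 lower, male 0.40, female -0.07), 0.25 for insulin secretion (87.5, male 0.32, female 0.00), where Rab3a (-1.53) and Scg2 (-3.06) were lower, and 0.13 for glucose metabolism (78.2, male 0.17, female -0.08). It was -0.03 for oxidative phosphorylation (39.5, male -0.03, female 0.07), 0.42 for interferon and antigen presentation (97.4, male 0.15, female 0.61) and 0.28 for cell cycle genes (69.0, male 0.02, female 0.66). For neuronal genes it was 0.19 (74.4, male 0.42, female -0.31) and for antioxidant and hypoxia genes 0.22 (91.0, 6 of 16 higher, male 0.08, female 0.72). Mitochondrial transcripts took 0.502% of the UMIs of control and 1.73% of those of Isl1CKO beta-like cells. With CPM not scaled by TMM every ratio of this comparison would be 1.13 higher, and without hormone genes in the totals 0.24 lower. Signs of medians within that range therefore depend on the scaling, and the percentiles were computed with TMM only.

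**Figure D4:**
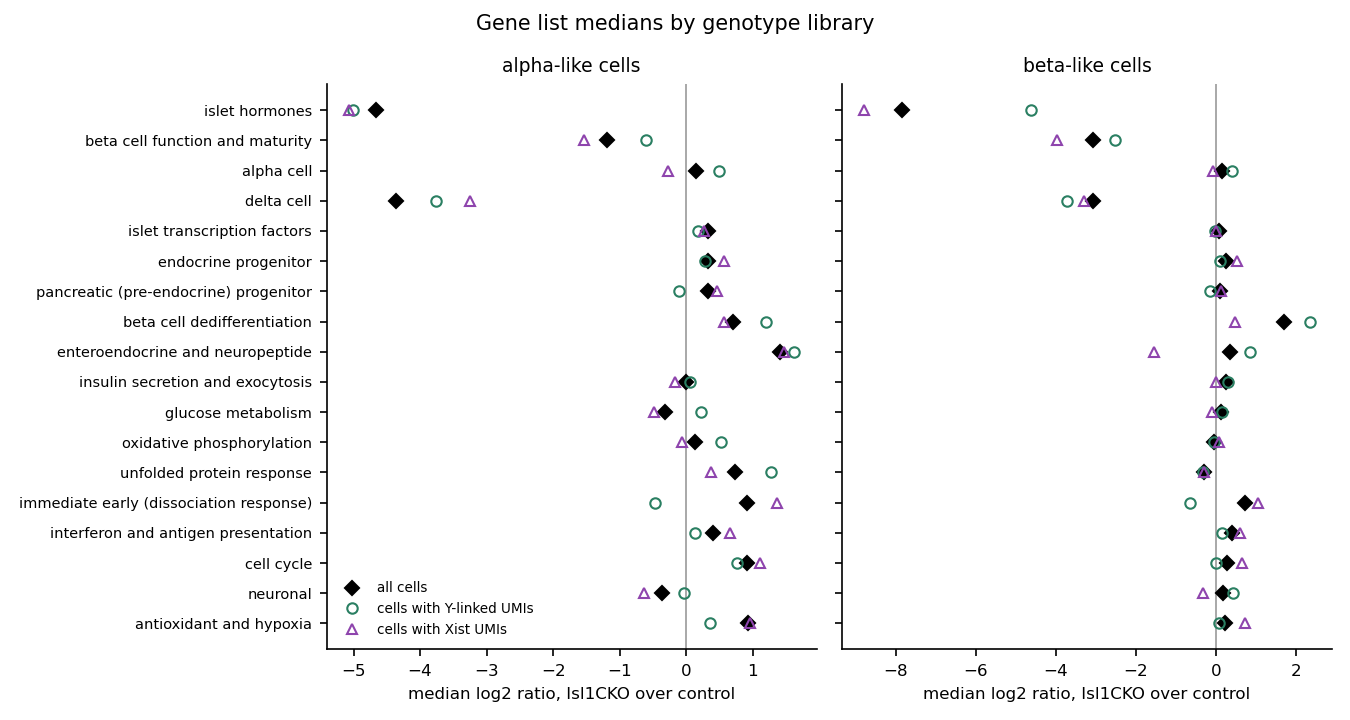
Median log2 ratio, Isl1CKO over control, of each gene list in alpha-like (left) and beta-like (right) cells, over all cells (diamonds), male cells (circles) and female cells (triangles). Beta cell function genes lie at -1.19 and -3.06 over all cells, and the immediate early list lies on opposite sides of 0 in male and female cells of both classes; another scaling moves all medians by up to 0.39 or -0.31 (left) and by up to 1.13 or -0.24 (right), so those nearer to 0 change sign.

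Across genes the genotype ratios of male and female cells were related but not alike. Pearson's r across 5917 genes was 0.72 over all endocrine cells, with 0.61 over 5755 genes in alpha-like and 0.64 over 2280 genes in beta-like cells. Genes are not independent replicates, and 69.9%, 65.7% and 62.7% of them had the same sign in both sexes. Between the sexes of the control library 0.270% of genes were at least 2-fold apart over all endocrine cells, 0.191% in alpha-like and 1.45% in beta-like cells. In Isl1CKO the shares were 9.18%, 13.3% and 8.60%.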

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

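The tests of a sex difference shared by both genotypes and of the 3 explanations for Xist in the control pool were chosen only after the result was seen, as was the size of 0.4 used below; the tests of UMIs per cell and of clock phase were written before their results were seen.

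Several genotype ratios (log2, Isl1CKO over control) had opposite signs in male and female cells, each at least 0.4 from 0. The difference between the sexes was not tested, because each sex is part of 1 library per genotype. In alpha-like cells the immediate early list had a median of -0.47 in male and 1.37 in female cells, Igfbp4 was at -0.88 and 2.83, Mt1 at -0.73 and 4.02 and the tdTomato reporter at -0.47 and 3.07. In beta-like cells, with 112 male and 31 female control cells, the immediate early list was at -0.64 and 1.06. The enteroendocrine and neuropeptide list was there at 0.86 and -1.54, and Gast at 4.51 and -2.25. In female beta-like cells a gene with 0 UMIs in both libraries would score -4.84. These negative values of the list and of Gast may therefore come from the 1 added to each count. Over all endocrine cells Gast was at 2.66 and -1.11. Among kept Isl1CKO cells, 2.09% lay in a cluster named acinar-like and left out of the comparisons, at 0.277% in control, and these cells also held the endocrine granule transcript Chga at 58031 CPM without scaling, against 70836 CPM in Isl1CKO endocrine cells.

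Isl1CKO cells with Xist UMIs and Isl1CKO cells with Y-linked UMIs fell in separate clusters. A sex difference shared by both genotypes is argued against, since 0.191% of genes were at least 2-fold apart between the sexes in control alpha-like cells against 13.3% in Isl1CKO. A difference in UMIs per cell stays undecided. With alpha-like cells thinned to 3000 UMIs the Isl1CKO share was 13.0%, and 12.1% unthinned over the same cells and genes. These shares rest on UMIs summed over cells, which thinning changes little, and the cells were not clustered again after thinning. A difference in clock phase stays undecided. Output genes and opposite-phase genes lay 0.41 apart in their median female minus male log2 value (control -0.27), which the rule written beforehand counts against it. Leaving out 1 gene, a check not in that rule, gave 0.08 to 0.67, on both sides of its limit. An earlier or later collection of 1 sex therefore cannot be told apart from the same phase. An effect of Isl1 loss that differs by sex and differences between the pooled animals stay open and untested.

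Xist UMIs without Y-linked UMIs were found in 23.2% of control endocrine cells, a pool the labels describe as males. Free RNA in droplets is argued against: cells with Xist and Y-linked UMIs together were 0.176 times as frequent as independence gives. Carry-over from the Isl1CKO library is argued against as well, since 1.67% of these cells lay in clusters with more Isl1CKO cells, against 2.0% of cells with Y-linked UMIs. The 74 cells with both, where independence gives 420.3, are what separate male and female cells would give, so the control pool may have held female animals. No biological explanation was tested, and the sex of single animals is not analysed here.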

How the results depend on the processing

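Tests within female cells, of hormone shares within male cells, with a shared doublet threshold, with free RNA from the narrower acinar gene set or from insulin, and without the enterochromaffin-like or control-cluster cells were chosen only after the result was seen. No paired analysis was possible because each genotype has 1 library. For 151 single-gene ratios given in the text, 2472 values under other settings fell within the counting interval in 1530 cases, outside it in 923, and reversed a ratio of at least 2-fold in 19. For 18 other results, 210 of 257 values stayed within the interval and 47 left it. The scalings, the limits on UMIs, genes and mitochondrial share, kept doublets, thinning, equal weighting of cells and free RNA subtracted at the insulin-based 2.14% and 3.36% reversed 0 of the 151 ratios. Outside the 151 ratios, at the insulin-based shares Ins1 turned from -1.99 to a positive ratio in alpha-like cells, the cells and gene behind the estimate, with 0 control UMIs left. Ghrl in beta-like cells, with 0 control and 35 Isl1CKO UMIs, had 0 left in both. Settings for delta-like and gamma-like expression were not run, as Isl1CKO had fewer than 50 such cells. Counting error covers neither animals nor libraries, and 221 control beta-like cells, 31 of them called female, limit the depth of that comparison.

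Reversed log2 ratios within male cells were -0.82 for Igfbp4, -0.75 for Mt1 and -0.47 for tdTomato in alpha-like cells, and -0.14 for Gip, -0.25 for Junb and -0.14 for tdTomato over endocrine cells. Within female cells they were -2.25 for Gast and 0.66 for Neurog3 in beta-like cells, and -1.11 for Gast over endocrine cells. The value of Gast in beta-like cells may come from the 1 added to each count, with which a gene unseen in both libraries scores -4.84. With free RNA subtracted at the estimate of 29.2%, which like 11.1% is more than Gcg in control cells allows, alpha-like cells had 2.25 for Neurog3, 6.98 for Ppy, 5.73 for Pyy and 3.47 for Sst, and beta-like cells 4.65 for Gcg, 3.75 for Ppy and 4.34 for Pyy. At 11.1%, Sst was at 3.71 in alpha-like cells, and Gcg at 5.08 and Ppy at 4.17 in beta-like cells. In each of these the cause was not tested.

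The Isl1 expression ratio of -0.31 was 0.22 with unscaled CPM, -0.52 without hormone genes in the totals, -0.39 with free RNA subtracted, -0.38 within male cells, -0.0844 within female cells, -0.36 with cells weighted equally and -0.38 thinned. The median of beta cell dedifferentiation genes in beta-like cells was 3.04 with unscaled CPM, 2.88 with free RNA subtracted at 29.2% and 2.80 within male cells, where control cells with both Xist and Y-linked UMIs were kept; list members of at least 5 CPM were chosen again under each setting. That of endocrine progenitor genes over endocrine cells was 0.0705 without hormone genes in the totals. The cause was not tested.

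Hormone classes were compared as percentage points, Isl1CKO minus control, with 4.90 for insulin. With a 5% limit insulin was at 0.685, Sst at -30.3, Ppy at -26.6, 2 or more hormones at -15.0 and none at 89.9, and with 0.5% Ppy was at -51.4, 2 or more at -43.1 and none at 78.5. With doublets kept Gcg was at -49.9, Sst at -34.7 and 2 or more at -40.2. Within female cells Gcg was at -59.3, Sst at -24.6, Ppy at -38.7, 2 or more at -30.2 and none at 85.5, and within male cells insulin was at 9.19, Gcg at -44.6, Ppy at -48.6 and none at 78.8. Cell classes moved too: delta-like cells, 0.120% of Isl1CKO endocrine cells, were 0.0401% with at least 2000 UMIs and 1000 genes, 0.0408% with the OrdMag minimum and 0.634% with each library clustered on its own, where gamma-like cells were 0% (0 of 7569). Beta-like cells, 5.72% of control and 20.8% of Isl1CKO endocrine cells, were 5.81% and 31.7% with at least 2000 UMIs and 1000 genes, 8.77% and 16.9% with each library clustered on its own, and 8.05% and 27.8% with the shared doublet threshold. Unnamed control cells, 2.36%, were 0% at resolution 0.5 and with the shared threshold and 4.28% with doublets kept. The cause was not tested.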

Other observations

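Both tests of why beta-like cells were few in the control library were chosen only after the result was seen.

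Digestive enzyme and gut hormone genes led 2 small clusters of the Isl1CKO library. Acinar-like cells, named from digestive enzyme genes, were 172 of 8231 kept Isl1CKO cells (2.09%, 1.79 to 2.42) and 11 of 3970 control cells (0.277%, 0.138 to 0.495), from pools sorted for tdTomato. They also held endocrine transcripts. Chga was found in 100% of the 172 cells at 58031 CPM without scaling, against 70836 CPM in Isl1CKO endocrine cells. Chgb was at 24029 against 22805 CPM and Ttr at 11586 against 43017 CPM. In the 11 control cells Chga was at 11763 CPM, against 10028 CPM in control endocrine cells. Among the Isl1CKO acinar-like cells of known sex 93.4% were female, and 1 of the 172 lay past the doublet threshold of the control library. A further 7 Isl1CKO cells formed cluster 16, counted among the endocrine cells and called enterochromaffin-like from 5 fixed markers although Gip and Ghrl led its genes, and 0 of 3970 control cells did, which allows a share of up to 0.0929%. The gut hormone genes Ghrl, Gip and Cck were at 90128, 22717 and 10034 CPM in them, with Gip UMIs in 42.9% and Ghrl UMIs in 28.6% of the 7 cells. Tph1, the enzyme of serotonin synthesis, was at 2579 CPM with UMIs in 28.6% of them.

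Clock genes differed between female and male alpha-like cells of the Isl1CKO library more than in control. Per1 and Per2, repressors of the circadian clock, were higher in female cells by 2.66 and 2.67 on the log2 scale and Ciart by 3.46, while Dbp was at -0.23. Across the output genes the median was 1.29 in Isl1CKO and -0.21 in control alpha-like cells, and across the opposite-phase genes 0.88 and 0.06. In Isl1CKO beta-like cells these medians were 0.80 and 1.53. The tdTomato reporter had a log2 ratio of 1.78 between genotypes over endocrine cells, with -0.14 in male and 2.90 in female cells. A tdTomato UMI was found in 99.04% of control and 99.8% of Isl1CKO endocrine cells (medians of 8903 and 8502 UMIs), in 92.4% and 98.6% after thinning, and in 67.4% and 71.4% of cluster 15 cells (medians of 5560 and 3371 UMIs). In the Isl1CKO library 36 cells lay in clusters with more control cells, 17 of them beta-like with a median of 27443 UMIs, and 0 of the 36 shared a barcode with a kept control cell.

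Beta-like cells were few in the control library, at 221 cells (218 to 345 under other filters and clusterings). Removal by the filters on barcodes is argued against as the whole cause: insulin took at least 1% of UMIs in 8.44% of all control barcodes of 500 or more UMIs, kept and removed, against 7.25% of the kept. Removed control barcodes had it more often, in 16.6%, and in 21.8% of those removed by the UMI, gene or mitochondrial limits (median 775 UMIs; 5.58% in Isl1CKO), so removal of some beta cells stays open. A loss of beta cells that broke open before capture stays undecided, as insulin was enriched 1.42 times in free RNA over control endocrine cells and Gcg, Sst and Ppy together 0.946 times, a relative enrichment of 1.4998, just under the bound of 1.5 set for it. Such a loss may have lowered the number and cannot be told apart here from the yield of the sort, which was not tested, and no biological explanation was tested.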
